A study of Beauveria bassiana with 6 samples.

How the data were processed

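RNA of Beauveria bassiana SAN01 was measured in 6 libraries, 2 for each of 3 conditions. Groups and replicate numbers were taken from the sample titles, and media from the descriptions. Per the labels' protocols, total RNA was isolated with an RNeasy kit and libraries were made with the Nextera DNA Flex kit, which does not mark strand. Reads of overlapping or antisense genes could therefore not be told apart. Nothing in the labels states poly(A) selection or removal of ribosomal RNA.

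The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.2, Salmon 1.5.2 and DESeq2 1.18.1, with no parameters. The genome build and annotation release behind the transcript index were not given in the sources used here. Each library had a deposited table with estimated counts of reads per transcript, TPM (abundance scaled by effective length), and lengths. Per the file headers these columns have the layout that Salmon writes, and nearly all of the estimated counts that the authors deposited were whole numbers, with 0 to 37 exceptions per library. The TPM values were made by the authors' quantification and were used here only in 1 alternative test. The effective lengths that the authors deposited were used only as offsets in another alternative. Estimation of this kind splits reads between near-identical copies, so values of gene families such as the hsp70, ribosomal protein and ABC transporter genes are uncertain where copies are alike. The authors also deposited 3 tables of their own comparisons, with log2 fold changes and adjusted p-values, per the file headers. These deposited tables held only genes with an adjusted p-value of at most 0.0499. In these tables the authors' deposited log2 fold changes were positive in the group named first in the comparison, which the counts bore out, and signs were turned where needed so that basal is the reference. Text copies of the same tables matched them in log2 fold change within 1e-06 and were not used.

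Transcripts were linked to locus tags through a table of RefSeq genes of assembly ASM28067v1, which matched all 10364 transcripts. No coordinates are given, because the files name no build. All transcript lengths were multiples of 3, so lengths are coding lengths. Product descriptions were available only for the 505 genes in the authors' deposited tables, 442 of them not hypothetical. The 32 gene lists were fixed as word patterns before the data were examined, and, apart from the oosporein cluster set by locus tags, they could find members only among these genes. That is a departure from the plan, which assumed descriptions for all genes. Hemicellulose degradation and mitochondrial ribosomal proteins had no member, and lipases and esterases, iron uptake and the oosporein cluster (a pigment gene cluster) had members but none tested. A word pattern can take in genes of another function: the cellulose list holds beta-1,3-glucan enzymes, the lipase list a transcription factor and the nitrogen list a phenylalanine ammonia-lyase. It can also miss genes: the hemicellulose pattern covers glycosyl hydrolase family 53 only with the word family. BBA_03167, annotated as glycosyl hydrolase 53 without that word, therefore entered only the list of all glycoside hydrolases. A list without members does not show that such genes were absent.

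Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr was applied by group, with a minimum count of 10 at the median library size. Its bar scales with depth, so it was under 10 reads in the basal libraries and above 10 in the fermentation libraries. The filter left 519 genes, 330 of them with a product description. These held 67.1% and 66.1% of the reads in the endophytic libraries, 50.5% and 50.0% in fermentation, and 91.7% and 50.8% in basal. TMM factors lay between 0.645 and 1.35, and CPM values are relative to the reads in tested genes times these factors, so a CPM share in a basal library exceeds the plain share of its reads. All 6 libraries entered 1 quasi-likelihood fit with a term per group, with 3 residual degrees of freedom and a biological coefficient of variation of 0.167. The prior degrees of freedom were infinite, so each gene was tested with a spread estimated over all genes and not with its own. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each SE of a log2 change was worked back from the test, as the size of the change divided by the square root of its F statistic. An SE therefore adds nothing beyond the change and its p-value. The 9 lists with at least 5 tested members were tested with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01, against the tested genes with a product description, since no other gene could have entered a list. Called members are also given as adjusted over the list alone.

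The genes named were fixed by a rule set before the data were examined: for each comparison, the 6 largest rises and 6 largest falls among called genes with a product description, a mean of at least 5 CPM over the 6 libraries and no overlap between the groups, and for each list the 2 called members with the smallest adjusted p. Genes outside this rule are said to be so. Where a group had 0 reads, the fold is a lower bound against a floor of 3 reads over the group. Where it had 1 to 3 reads, the pooled ratio is given with a 95% exact binomial interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

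The steps were tested on simulated counts with 200 of 519 genes changed, drawn 20 times. All libraries were drawn from a single mean profile with the dispersion of the fit itself. The simulations therefore leave out differences in composition within a group, such as that between basal replicates 1 and 2. Their share of false calls holds only where the model of the fit does. For endophytic against basal, 15.4% of 2-fold, 60.7% of 4-fold and 79.8% of 8-fold changes were recovered, and 3% of calls were unchanged genes. For fermentation against basal the values were 19.6%, 69.1%, 86% and 2.4%, and for endophytic against fermentation 51.5%, 93%, 98.6% and 2.5%. In simulated lists of 10 genes moved 4-fold among 250 genes, for endophytic against fermentation, 100% were recovered and 0.5% of unmoved lists were called, both at an unadjusted p under 0.05, which is looser than the adjusted threshold used for lists.

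Alternatives planned before the data were examined were median-of-ratios, upper-quartile and no composition factors, effective-length offsets, no filter on low counts, a minimum of 50 reads in 2 libraries, DESeq2 1.42.0, limma on log2(TPM + 1), limma-voom, a test against a 2-fold change, only the 2 groups compared, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Alternatives added after seeing the data were thinning of all libraries to the reads of the smallest, all tested genes as background of the list test, and subtraction of a flat background per coding base from basal replicate 2.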

Results

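The series measured RNA of Beauveria bassiana SAN01, a filamentous fungus that kills insects and also lives inside plants, by sequencing of libraries made from total RNA. Cultures stood for 3 trophic conditions with 2 libraries each. The endophytic libraries came from growth in extract of banana corm, the underground stem of the plant, freeze-dried for replicate 1 and crude liquid for replicate 2. The fermentation libraries came from wheat bran for replicate 1 and oatmeal for replicate 2. Both basal libraries came from potato dextrose medium, which the labels call agar in the descriptions and broth in the growth protocol. The series title names the breakdown of plant biomass as its subject.

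Reads assigned to transcripts were few and differed between the groups. The endophytic libraries held 23788 and 21321 reads, the fermentation libraries 109075 and 322153, and the basal libraries 6413 and 12355. At least 1 read fell on 3594 and 3520 genes in the endophytic libraries, on 7165 and 8536 in the fermentation libraries and on 675 and 4187 in the basal libraries, of 10364 genes. Depth and group could not be separated, because every fermentation library was deeper than every other library. A count of 0 allowed up to 3 reads, which were 791 CPM (depth-scaled counts) in basal replicate 1 and 641 in basal replicate 2, against 41.8 and 13.9 in the fermentation libraries. The 10 most read genes took 70.5% (95% exact binomial interval 69.4 to 71.6) of the reads of basal replicate 1 and 34.2% (33.3 to 35) of those of basal replicate 2. The same share was 30.0% (29.4 to 30.6) and 29.3% (28.7 to 29.9) in the endophytic libraries, and 9.25% (9.08 to 9.42) and 8.88% (8.78 to 8.98) in the fermentation libraries. The 2 endophytic libraries came from different media and so from separate cultures, as did the 2 fermentation libraries. Their spread includes the difference between media. Nothing in the labels says that the 2 basal libraries were separate cultures, so their spread may be technical. P-values rest on a spread estimated over all genes and groups, not on that of each gene. A gene whose libraries lay far apart, as many did between the 2 basal libraries, was given no larger spread for it.

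**Figure D1:**
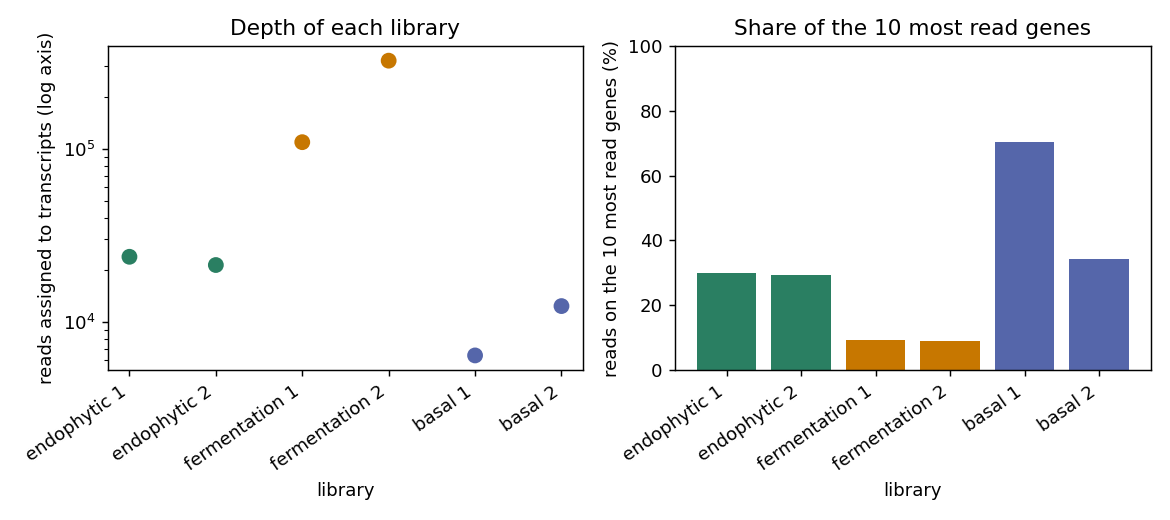
The left panel plots reads assigned to transcripts in each of the 6 libraries on a log axis, and the right panel plots the percent of those reads on the 10 most read genes of that library, as bars from 0. The basal libraries sit lowest in depth (6413 and 12355 reads) and basal replicate 1 has the highest share on 10 genes (70.5%).

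Between the endophytic and basal conditions, the GATA factor BBA_02538, of a zinc finger family that includes regulators of nitrogen use, had 65 and 67 endophytic reads against 0 and 0 basal reads, at least 11.4-fold higher (adjusted p = 1.27e-07, edgeR quasi-likelihood test). The peptide transporter BBA_05835 had 58 and 58 reads against 0 and 0, at least 10-fold higher (adjusted p = 6.89e-07). The bZIP transcription factor BBA_06272 rose by 4.09 on the log2 scale (SE 0.61, adjusted p = 1.2e-09), from 477 ± 70.5 CPM in basal, where it had 2 and 2 reads, to 8105 ± 1929 CPM (SD, n = 2). Hsp90, the chaperone BBA_06516, fell by 2.69 on the log2 scale (SE 0.20, adjusted p = 4.45e-38), from 215470 ± 16974 to 33288 ± 908 CPM (SD, n = 2).

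Of the ABC transporters, pumps that move diverse compounds across membranes, 5 of 10 tested members were higher in the endophytic libraries, 0 lower and 5 not called, with 5 called when adjusted over the list alone. The ABC-2 type transporter BBA_01781 rose by 3.63 (SE 0.59) and the multidrug resistance protein BBA_04936 by 2.97 (SE 0.64) on the log2 scale, from 0 and 5 and from 1 and 4 basal reads. The camera set test gave the list an adjusted p of 0.0195, and an adjusted p = 0.393 with an estimated correlation, and without endophytic replicate 1 there were 3 higher. Of the transcription factors, 7 of 12 were higher, 1 lower and 4 not called, with 8 called when adjusted over the list alone (camera adjusted p = 0.0273; adjusted p = 0.318 with an estimated correlation), and without basal replicate 1 there were 4 higher. Of the list for cellulose degradation, 0 of 5 were higher, 3 lower and 2 not called, also 3 when adjusted over the list alone (camera adjusted p = 0.0273; adjusted p = 0.318 with an estimated correlation). The 3 lower members were BBA_08499 and BBA_01743, annotated as glucan 1,3-beta-glucosidases, and the beta-glucosidase BBA_08017. Enzymes of the 1,3-beta-glucan type act on glucan of the fungal wall, among other substrates, and not on cellulose. BBA_08499 fell by 3.48 (SE 0.53, adjusted p = 4.76e-09) and BBA_08017 by 2.94 (SE 0.75) on the log2 scale, and BBA_01743, named after its value was seen, by 2.33 (SE 0.61). The call of BBA_08017 ended without endophytic replicate 2, without a filter on low counts and with limma on log2(TPM + 1), which also ended that of BBA_01781. Apart from the oosporein cluster, all lists held only genes from the authors' deposited tables, which were chosen on these samples. No list count is therefore independent evidence of its direction. Of the 330 tested genes with a product description, from which tested members came, 114 were called in this comparison.

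Of the other lists, those large enough for the set test did not pass it. All 3 tested members of the list for the glyoxylate cycle, fatty acid oxidation and gluconeogenesis were higher in the endophytic libraries, also 3 when adjusted over the list alone. Phosphoenolpyruvate carboxykinase BBA_02833, an entry enzyme of gluconeogenesis, rose by 1.93 on the log2 scale (SE 0.41, adjusted p = 5.36e-05), from 2707 ± 101 to 10305 ± 1369 CPM (SD, n = 2). Without basal replicate 2 or without endophytic replicate 1 only 1 of the 3 was called, and without basal replicate 1 there were 2. Of amino acid and peptide uptake, 3 of 6 were higher and 0 lower, with 3 adjusted over the list alone (camera adjusted p = 0.107; adjusted p = 0.402 with an estimated correlation). Of the cytochromes P450, oxidising enzymes of many pathways, 0 of 6 were higher, 3 lower and 3 not called, with 4 adjusted over the list alone (camera adjusted p = 0.116), and 1 was lower without endophytic replicate 1 or without either fermentation library. CYP6001C8, BBA_03825, had 0 and 0 reads against 3 and 6, at least 11.6-fold lower (adjusted p = 7.15e-05). Of the secondary metabolism list, 1 of 10 was higher, 4 lower and 5 not called, with 5 adjusted over the list alone (camera adjusted p = 0.116); without basal replicate 2 there were 1 higher and 1 lower, and without endophytic replicate 1 or 2 there were 0 higher and 1 or 2 lower. None of the 7 tested extracellular-type proteases was called by edgeR over all genes or over the list alone, and 1 was lower without basal replicate 1.

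Heat shock and chaperone genes went both ways, with 2 of 11 higher, 3 lower and 6 not called, and 6 called when adjusted over the list alone. Their median log2 change was 0.33 and their mean 0.15, while camera placed them below the other annotated genes (adjusted p = 0.116). With upper-quartile factors 0 were higher and 4 lower, and leaving out each library gave 0 to 2 higher. The heat shock protein 70-2 gene BBA_05586 fell by 2.00 on the log2 scale (SE 0.16, adjusted p = 2.83e-32), with 2241 and 1963 reads against 2320 and 1952 at the lower basal depth. Its call ended with limma on log2(TPM + 1) and without a filter on low counts. The glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase BBA_05480 fell by 2.51 (SE 0.29, adjusted p = 2.12e-15). Alongside these genes, 20 genes of conserved function, picked after the data were seen and including BBA_05586 and BBA_06516, held 74.6% (95% exact interval 73.5 to 75.6) and 35.8% (35 to 36.7) of the basal reads, and 31.3% (30.7 to 31.8) and 30.8% (30.2 to 31.5) of the endophytic reads.

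In all, 130 of 519 tested genes differed between endophytic and basal, 79 higher and 51 lower, and 184 had an unadjusted p under 0.05. The split depended on scaling, with 46 higher and 64 lower under upper-quartile factors and 150 and 34 with no composition factor. DESeq2, which changes the test as well, gave 42 and 56. The median log2 change of all tested genes was 0.55, against 0.15 under upper-quartile factors and 1.19 with no composition factor, while the cellulose list had 0 higher and 3 lower under all 4 scalings tried and ABC transporters had 4 to 8 higher and 0 lower. Without basal replicate 2 the median was 4.12 over 775 tested genes and 6 of the 130 calls turned sign, with 85 calls, 50 higher and 35 lower. Without endophytic replicate 1 there were 72, and without endophytic replicate 2 there were 74.

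Between the fermentation and basal conditions, the exoglucanase precursor BBA_00792, a beta-1,3-glucan enzyme, had 659 and 2301 fermentation reads against 0 and 2 basal reads, a ratio of 43.5 after scaling for depth (95% exact interval 12.03 to 359, adjusted p = 3.04e-14). The adhesin Mad1, BBA_02419, named for a surface protein that attaches fungal spores to insect cuticle, rose by 3.27 on the log2 scale (SE 0.65, adjusted p = 5.66e-06), from 452 ± 267 CPM, which were 1 and 3 basal reads, to 4534 ± 1861 CPM (SD, n = 2). The ribosomal protein gene BBA_05415, of the L10-A type, fell by 4.56 (SE 0.43, adjusted p = 2.25e-23), from 7331 ± 1421 to 315 ± 27.4 CPM (SD, n = 2).

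All 7 of 7 tested extracellular-type proteases were higher in fermentation, also 7 when adjusted over the list alone, in genes chosen on these samples. Under upper-quartile factors 5 of these 7 proteases were higher, and under the other scalings all 7. The camera test placed them above other annotated genes with an adjusted p of 0.08, short of the threshold. Of the 330 tested genes with a product description, from which tested members came, 217 were called in this comparison. The alkaline serine protease genes BBA_08791 and BBA_09176, both annotated AorO, had 248 and 729 reads against 0 and 1, a ratio of 28.7 (95% exact interval 5.14 to 1135), and 283 and 755 against 0 and 2, a ratio of 15.3 (4.21 to 126). Outside that list, the family S53 protease BBA_07631 had 166 and 541 reads against 0 and 0, at least 6.92-fold higher (adjusted p = 8.87e-06). Of hydrophobins and adhesins, 3 of 4 were higher and 0 lower, with 3 adjusted over the list alone. Hydrophobin 2, BBA_00530, a small protein of the type that coats spores, had 232 and 761 reads against 2 and 0, a ratio of 14.6 (4.03 to 121). Of amino acid and peptide uptake, 3 of 6 were higher and 0 lower, with 3 adjusted over the list alone (camera adjusted p = 0.441). The oligopeptide transporter BBA_06420 had 125 and 388 reads against 0 and 0, at least 5.02-fold higher.

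Of the secondary metabolism list, 6 of 10 were higher, 0 lower and 4 not called, with 9 adjusted over the list alone (camera adjusted p = 0.0889; adjusted p = 0.594 with an estimated correlation). The non-ribosomal peptide synthase BBA_08222, of the enzyme class that assembles peptides without ribosomes, rose by 2.64 on the log2 scale (SE 0.44, adjusted p = 6.9e-08), with 523 and 2778 reads against 0 and 14. Of the cellulose degradation list, 3 of 5 were higher and 0 lower, with 3 adjusted over the list alone (camera adjusted p = 0.441), and 1 of these was the beta-1,3-glucan enzyme BBA_00792. Of fungal wall synthesis, 3 of 4 were higher, with 3 adjusted over the list alone and only 1 under upper-quartile factors. The catalytic subunit of beta-1,3-glucan synthase, BBA_10207, rose by 3.18 (SE 0.65, adjusted p = 1.24e-05), from 1 and 3 basal reads. Of the cytochromes P450, 4 of 6 were higher and 1 lower, with 5 adjusted over the list alone (camera adjusted p = 0.56). Without basal replicate 1 there were 1 higher and 0 lower, and without fermentation replicate 2 there were 2 higher and 0 lower. Of the transcription factors, 5 of 12 were higher and 0 lower, with 5 adjusted over the list alone (camera adjusted p = 0.441), against 3 when any library but endophytic replicate 2 was left out. Under upper-quartile factors 2 transcription factors and 1 cytochrome P450 were higher. With limma on log2(TPM + 1) the calls of BBA_00792, BBA_00530, BBA_08791, BBA_09176 and BBA_08222 ended.

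Cytosolic ribosomal protein genes had 0 of 15 higher, 12 lower and 3 not called, and 13 called when adjusted over the list alone. Camera gave an adjusted p of 3.95e-08, and an adjusted p = 0.412 with an estimated correlation. Under the other scalings 10 to 14 of the 15 were lower and 0 higher, and without basal replicate 1 there were 8. The 40S protein S9 gene BBA_07729 fell by 3.32 (SE 0.50, adjusted p = 1.52e-09). Of the respiratory chain, 3 of 4 were lower and 0 higher, with 4 adjusted over the list alone, and ATP synthase protein 9, BBA_01534, fell by 4.40 (SE 0.68, adjusted p = 4.31e-09). Heat shock and chaperone genes again split, with 4 of 11 higher, 5 lower and 2 not called, and 10 called over the list alone. Their median log2 change was 0.30 and their mean 0.23, while camera placed them below the other annotated genes (adjusted p = 0.0889). Heat shock protein 70-2, BBA_05586, fell by 4.09 (SE 0.17) and Hsp90, BBA_06516, by 4.50 (SE 0.21), and the ubiquitin gene BBA_03881 fell by 6.22 (SE 0.38, adjusted p = 6.62e-54). The ABC transporters had 3 of 10 higher, 1 lower and 6 not called, with 4 over the list alone, and their median of 0.96 and mean of 1.11 stood against a camera direction below the other genes (adjusted p = 0.511). Upper-quartile factors gave 1 higher and 2 lower of these transporters, and 2 higher and 5 lower of the heat shock genes. Without fermentation replicate 2 there were 0 ABC transporters higher, without basal replicate 1 there was 1, and without basal replicate 2 there were 2 heat shock genes higher. The 20 conserved genes held 5.40% (95% exact interval 5.26 to 5.53) and 5.11% (5.03 to 5.18) of the fermentation reads, against the basal shares given above.

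In all, 257 of 519 genes differed between fermentation and basal, 191 higher and 66 lower, and 297 had an unadjusted p under 0.05. Upper-quartile factors gave 99 higher and 80 lower and no composition factor gave 330 and 42, while the median log2 change of all tested genes was 1.41 in the main scaling, 0.79 with upper-quartile factors and 2.32 with no composition factor. Without basal replicate 2 the median was 6.81 over 775 tested genes and 4 of the 257 calls turned sign, with 201 calls, 147 higher and 54 lower, and without basal replicate 1 the median was 0.92. With all libraries thinned to 6413 reads, an alternative chosen after seeing the data, the median was 69 calls among 102 tested genes.

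Between the endophytic and fermentation conditions, the cuticle-degrading protease bassiasin I, BBA_00443, a secreted enzyme that digests insect cuticle protein, had 0 and 0 endophytic reads against 169 and 552 fermentation reads, at least 27.3-fold lower (adjusted p = 6.57e-15). Hydrophobin 2, BBA_00530, had 0 and 0 reads against 232 and 761, at least 37.6-fold lower (adjusted p = 3.55e-18). The calcium-transporting ATPase BBA_03179 had 44 and 36 reads against 0 and 2, a ratio of 352 after scaling for depth (95% exact interval 94.4 to 2958, adjusted p = 6.47e-37). The potassium or sodium efflux ATPase BBA_04957 rose by 5.23 on the log2 scale (SE 0.40, adjusted p = 5.17e-36), from 229 ± 28.6 CPM in fermentation to 8903 ± 895 CPM (SD, n = 2).

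Of the extracellular-type proteases 0 of 7 were higher and 7 lower in the endophytic libraries, also 7 when adjusted over the list alone (camera adjusted p = 0.0205; adjusted p = 0.416 with an estimated correlation). The AorO genes BBA_09176 and BBA_08791 had no endophytic read and were at least 39.3-fold and at least 37.0-fold lower. All 5 of 5 members of the cellulose degradation list were lower, also 5 over the list alone (camera adjusted p = 0.0376; adjusted p = 0.416 with an estimated correlation), and 3 of them, BBA_00792, BBA_01743 and BBA_08499, are annotated as beta-1,3-glucan enzymes. BBA_00792 stood at 0.00892 times its fermentation level (95% exact interval 0.00184 to 0.0261), and the beta-glucosidase BBA_08017 fell by 4.83 on the log2 scale (SE 0.51, adjusted p = 1.69e-19). As in the other comparisons, these members came from tables chosen on these samples and are not independent evidence. Of the 330 tested genes with a product description, 303 were called in this comparison. A list with nearly all of its members called is therefore no finding about that list.

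Of secondary metabolism, 1 of 10 was higher and 9 lower, with 10 called over the list alone (camera adjusted p = 0.0524; adjusted p = 0.533 with an estimated correlation). The non-ribosomal peptide synthetase BBA_07611 had 0 and 0 reads against 220 and 508, at least 27.6-fold lower. The beauvericin biosynthetic gene BBA_09727, beauvericin being a cyclic peptide toxin, fell by 2.48 (SE 0.48, adjusted p = 8.82e-07). All 4 of 4 hydrophobins and adhesins were lower, also 4 over the list alone, and Mad1, BBA_02419, fell by 2.65 (SE 0.42, adjusted p = 1.87e-09). Of the cytochromes P450, 1 of 6 was higher and 5 lower, with 6 over the list alone (camera adjusted p = 0.232), the higher member was not called without endophytic replicate 2 or without either fermentation library, and CYP6001C8, BBA_03825, was at least 37.6-fold lower. Fungal wall synthesis had 3 of 4 lower and 0 higher, with 3 over the list alone, and glucan synthase BBA_10207 fell by 1.73 (SE 0.38). With limma on log2(TPM + 1) the calls of BBA_00530, BBA_00792, BBA_02419, BBA_09727 and BBA_10207 ended, and limma-voom also ended those of BBA_02419 and BBA_09727.

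Of the ABC transporters, 8 of 10 were higher in the endophytic libraries and 2 lower, with 10 over the list alone (camera adjusted p = 0.0205; adjusted p = 0.416 with an estimated correlation). BBA_08160 rose by 5.11 (SE 0.47, adjusted p = 1.25e-24), a call that ended with limma on log2(TPM + 1), and BBA_06276 by 2.81 (SE 0.28, adjusted p = 2.89e-22). All 15 of 15 cytosolic ribosomal protein genes were higher, also 15 over the list alone (camera adjusted p = 0.000191; adjusted p = 0.416 with an estimated correlation), and the S7 gene BBA_04051 rose by 2.59 (SE 0.40). All 4 of 4 respiratory chain genes were higher, also 4 over the list alone but 2 without fermentation replicate 2, and the ATP synthase alpha chain BBA_00154 rose by 1.92 (SE 0.34, adjusted p = 7.55e-08). Alongside these rises, the 20 conserved genes, which include BBA_00154 and no ribosomal protein gene, held 31.3% and 30.8% of the endophytic reads against 5.40% and 5.11% of the fermentation reads, with the intervals given above. All 3 of 3 genes of the glyoxylate cycle, fatty acid oxidation and gluconeogenesis were higher, with 2 under median-of-ratios factors or no composition factor and 1 without endophytic replicate 1 or without fermentation replicate 2, and BBA_02833 rose by 1.89 (SE 0.31). Amino acid and peptide uptake had 3 of 6 higher and 3 lower, with 6 over the list alone, and its median of -0.21 and mean of -1.17 stood against a camera direction above the other genes (adjusted p = 0.64). The transcription factors had 7 of 12 higher, 4 lower and 1 not called, with 11 over the list alone (camera adjusted p = 0.243). Without fermentation replicate 2 there were 4 higher and 2 lower, and without endophytic replicate 2 there were 2 lower. Heat shock and chaperone genes had 4 of 11 higher, 5 lower and 2 not called, with 9 over the list alone, and their median of -0.49 and mean of -0.08 stood against a camera direction above the other genes (adjusted p = 0.64). Without endophytic replicate 1 there were 3 lower. Of the chaperones, the hsp70-like gene BBA_00257 rose by 3.08 (SE 0.29) and heat shock protein 70-2, BBA_05586, by 2.09 (SE 0.16).

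**Figure D2:**
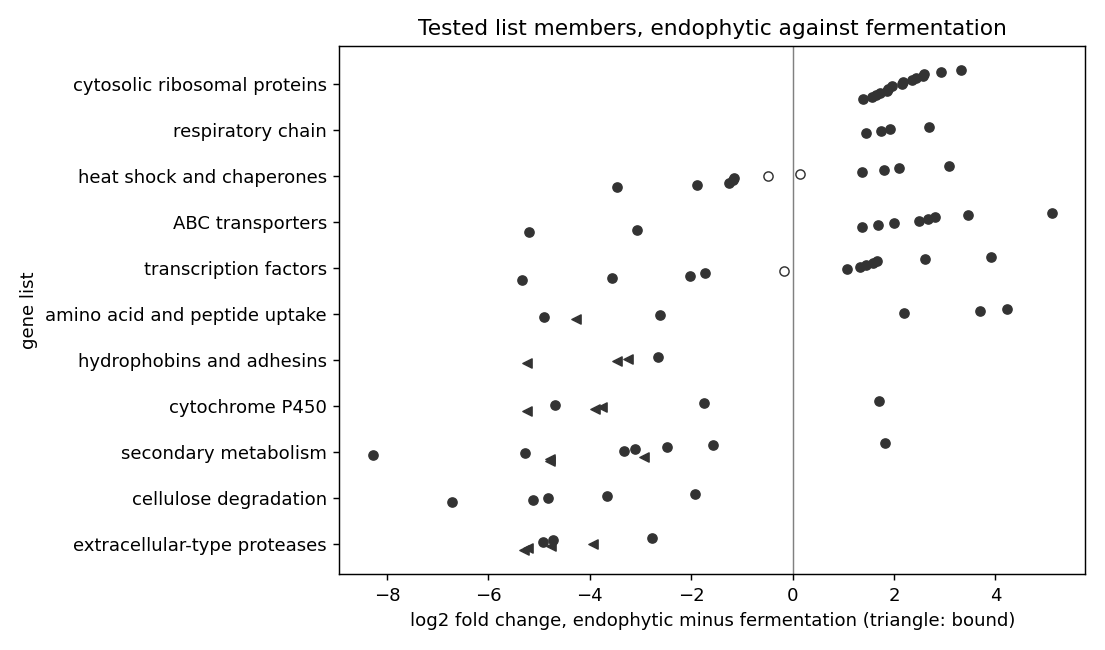
Each point is a tested member of a gene list, placed at its log2 fold change between endophytic and fermentation (x axis, endophytic minus fermentation, 2 libraries each), with lists on the y axis; filled points had an adjusted p under the 0.05 threshold and triangles mark genes with no endophytic read, drawn at the bound that 3 reads allow. All 7 proteases and all 4 hydrophobins and adhesins lie left of 0, and all 15 ribosomal protein genes lie right of 0.

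In all, 351 of 519 genes differed between endophytic and fermentation, 140 higher and 211 lower in the endophytic libraries, and 367 had an unadjusted p under 0.05. Thinning of all libraries to 6413 reads left a median of 65 calls among 102 tested genes, limma on log2(TPM + 1) gave 131 calls, and the 4 libraries alone gave 725 among 1502 tested genes. The counts for proteases, cellulose degradation, secondary metabolism, ABC transporters and ribosomal proteins were identical under all 4 scalings, while the median log2 change of all tested genes lay between -0.79 and -0.28.

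Genes called against basal in both conditions were counted next. Of the 519 genes, 41 were higher than basal in both, 20 lower in both and 11 called in both with opposite signs. With all libraries, basal included, redrawn from a single mean profile, 0.01 genes shared a call and a sign on average (SD 0.1, 100 simulations). Without an effect hardly any gene is called, so a count this low was fixed in advance. It is no baseline for the shared genes. Independent lists of these sizes would share 29.1 higher and 6.5 lower. Log2 fold changes against basal had a covariance of 5.94 across genes, against 1.08 (SD 0.257) simulated with no effect, a difference of 4.86, and their correlation across genes, which are not independent replicates, was 0.532 against 0.923 simulated. These simulations drew counts with the dispersion of the fit and leave out the difference in composition between the 2 basal libraries. With 2 basal libraries, no split would leave each comparison 2 of its own and none was made, so part of the excess may come from the shared controls. The shared genes with the same sign fell from 61 to 29 without endophytic replicate 1 and to 32 without basal replicate 2.

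The authors' deposited tables listed 85 genes between basal and endophytic, 178 between basal and fermentation and 444 between endophytic and fermentation. The authors' deposited table for endophytic had 50 genes higher and 35 lower than basal, that for fermentation 112 and 66, and that between the conditions 181 higher and 263 lower in endophytic. Of these, 79, 159 and 287 were among the genes tested here, 100% had the same sign in the edgeR fit (95% exact intervals from 95.4%, 97.7% and 98.7%), and 77, 157 and 286 were called. The deposited genes were selected on these same libraries, so a shared sign was largely fixed in advance and is no independent check of the fit. The intervals treat genes as independent trials, which they are not. The edgeR fit called a further 53, 100 and 65 genes that these tables did not list.

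The SD of the log2 CPM difference between the 2 libraries of a group, which depends on depth and on the prior count, was 0.39 for wheat bran against oatmeal, 0.83 for the freeze-dried against the crude corm extract, and 2.22 for the 2 basal libraries on the same medium, with a prior count of 2. By that measure 0, 22 and 221 of 519 genes were over 4-fold apart. A chi-square of the counts per degree of freedom, which treats reads as independent molecules and so tests only against counting noise, was 1.94 for the fermentation pair, 1.24 for the endophytic pair (p = 6.7e-06) and 2.64 for the basal pair (p = 1.44e-18). With 1 library per medium, differences between media had no replicate check.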

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

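The questions in this part and the limits set for them were chosen after the results they concern were seen. The scalings and the leaving out of libraries that it draws on had been planned. The effects of the 2 conditions against basal had opposite signs, each past the threshold, for 11 genes, and all 11 were below basal in the endophytic libraries and above it in the fermentation libraries. All 11 were also called between endophytic and fermentation, which follows from how they were chosen and is no separate evidence. They were listed for this sign pattern after their values were seen: the non-ribosomal peptide synthases BBA_07611, BBA_08222 and BBA_08424, the polyketide synthase BBA_08219, the cytochromes P450 BBA_02155 and BBA_03825, the beta-glucosidase BBA_08017, the glycosyl hydrolase BBA_03167, the GPI anchored protein BBA_00907 and the genes BBA_02140 and BBA_02352 without a described function. Several rest on few reads or on basal replicate 2: basal reads were 0 and 14 for BBA_08222, whose endophytic effect turned sign without that library, 1 and 10 for BBA_08219, and 0 and 3 for BBA_02155 and BBA_08424. BBA_02140 and BBA_07611 had 2 and 2 basal reads against 0 and 0 endophytic reads. The pattern also depended on scaling. Under upper-quartile factors 0 of 2 glycoside hydrolases were called higher in fermentation than in basal, so BBA_03167 lost it. In that setting 1 of 6 cytochromes P450, 2 of 5 members of the cellulose list and 5 of 10 of secondary metabolism were called higher in fermentation.

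Basal replicate 2 had low counts on many genes, with exactly 1 read on 2424 genes, against 411 in basal replicate 1. Among genes with at most 5 reads in each basal library, 1618 had no read in either fermentation library, and their reads per coding base in basal replicate 2 were 0.412 times (95% exact interval 0.362 to 0.467) those of 3501 genes of middle fermentation abundance, while the same ratio was 0.086 (0.0232 to 0.224) in basal replicate 1 and 0.0552 and 0.0687 in the endophytic libraries. Carry-over of reads from the fermentation libraries needed a ratio under 0.2, so the value argues against it as the whole source. Genomic DNA may add such reads and stays open, since 0.412 lies below the 0.5 set for it and reads outside coding sequence were not analysed. No biological explanation was tested, because both basal libraries came from the same medium; with a flat background subtracted, 172 genes were called for endophytic and 325 for fermentation against basal.

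A few conserved genes held a large share of the basal reads, and most of the reads in replicate 1 only: 20 such genes took 4782 of 6413 and 4426 of 12355 reads there, 7435 and 6576 in the endophytic libraries and 5885 and 16449 in the fermentation libraries. A heat shock response of the basal cultures would raise the chaperone genes as a set, but 3 of 11 were called higher in basal than in both other groups, and 4 of 11 were lower in basal than in fermentation. The latter count depended on scaling, with 2 under upper-quartile factors and 6 with no composition factor, while 5 were higher in basal than in fermentation in both. The 11 genes went both ways in each, but they came from tables chosen on these samples. For endophytic against basal 6 of the 11 were not called. In that comparison the simulations recovered 15.4% of 2-fold and 60.7% of 4-fold changes, so genes not called say little against a rise in basal. Reads of another organism at conserved sequence might add to these genes in the basal libraries and in the endophytic ones, where the share was 31.3% and 30.8%, against 5.40% and 5.11% in fermentation. The highest library exceeded the lowest by 3.72 times for these genes and 187 times for the other genes, a ratio of 50.4, but the genes were picked for this pattern and depth widens the second span, so the ratio decides nothing. That source and a true difference in expression between media cannot be told apart, because the files hold counts and no reads, and the media difference stays open as untested.

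More genes were above than below basal in the fermentation libraries, 74.3% of the calls. A difference in total reads as the whole cause is argued against by thinning of all libraries to the smallest, where the share of higher calls had a median of 71.3% and lay between 65.2% and 77.5% over 20 draws. This covers a median of 102 tested genes. Thinning did not even out the reads left for the other genes, since the 20 conserved genes held 74.6% of basal replicate 1 against 5.4% and 5.1% in fermentation. A lack of reads on those other genes in basal was thus not tested. The choice of scaling factor may set much of the excess, since the share lay between 55.3% and 88.7% over 4 scalings. It cannot be told apart from a difference between the media, because no scaling made rises and falls equal in number and the files hold no external standard.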

How the results depend on the processing

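Thinning, the all-gene list background and background subtraction were chosen after seeing the data, the other settings before. Main counts were 130 calls for endophytic against basal, 257 for fermentation against basal and 351 for endophytic against fermentation. Thinned to the smallest library they were 41, 69 and 65, as fewer reads and 102 genes were tested. For endophytic against basal, 74 genes passed against a 2-fold change, and leaving out each library gave 72 to 96. For fermentation against basal, counts were 413 without a filter, 110 at 50 reads in 2 libraries and 161 with limma on log2(TPM + 1). For endophytic against fermentation, they were 651 without a filter, 131 with limma on log2(TPM + 1) and 725 with the 4 libraries alone, which tested more genes; leaving out each library gave 276 to 473. With the replicate number as a replicate block, calls were 54, 169 and 316, called lists 1, 1 and 5, and shared genes 20 in place of 61; same-numbered libraries had correlations of deviations of -0.04, 0.30 and 0.01, so shared variation is not excluded for basal and fermentation, the pair at 0.30. Called lists were 3, 1 and 4: 0 each with an estimated correlation, 5, 8 and 8 with fry, which tests against no change and not against other genes, and 8, 4 and 5 with all tested genes as background, leaving out each library giving 1 to 4, 1 to 3 and 3 to 5. Shared genes were 29 to 37 when each library was left out. With a prior count of 10, the SD between libraries was 1.22 in basal, 0.51 in endophytic and 0.33 in fermentation. BBA_08222 in endophytic against basal lay between -9.67 and 4.12 on the log2 scale when each library was left out; the low end has no endophytic read, and the sign reversed without basal replicate 2, whose 14 reads are its only basal reads. Named genes kept direction and call in 496 of 583 alternative fits for endophytic against basal, 776 of 829 for fermentation against basal and 950 of 1008 for endophytic against fermentation, and lost the call in 86, 53 and 58. The sign of the deposited lists was shared at 100% with DESeq2 too, again on the libraries that the lists were selected on. A group of 1 library was assumed to vary like the others. Where no construction is given, the cause was not tested.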

Other observations

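The comparison in this part, and the genes named in it, were chosen after their values were seen. When the 4 endophytic and fermentation libraries were fitted without the shallow basal libraries, the edgeR test covered 1502 genes and called 725, 261 higher and 464 lower in the endophytic libraries. Transcription factors, with 7 members tested only in this fit, had 13 of 19 higher, 5 lower and 1 not called, and 18 called when adjusted over the list alone. The C2H2 zinc finger gene BBA_02935 rose by 3.73 on the log2 scale (SE 0.49, adjusted p = 1.78e-07). The hexokinase-like gene BBA_05632, of the family that phosphorylates sugars at the start of glycolysis, rose by 3.53 (SE 0.48, adjusted p = 1.85e-10), with 9 and 10 reads against 3 and 14 at the higher fermentation depth. The calcium/proton exchanger BBA_01399 rose by 3.54 (SE 0.48), beside the calcium pump BBA_03179 of the main comparison. The monooxygenase BBA_06196 had 15 and 6 endophytic reads against 0 and 3, and the fatty acid hydroxylase BBA_10134 had 10 and 8 against 0 and 2.

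Members tested only in this fit went both ways, with 3 of 5 new ribosomal protein genes higher in the endophytic libraries and 2 lower. Amino acid and peptide uptake had 3 of 10 higher and 7 lower, also 10 over the list alone, and all 4 newly tested members were lower, among them the oligopeptide transporter BBA_02451 with 0 and 0 reads against 38 and 155. Major facilitator transporters had 3 of 9 higher and 6 lower, also 9 over the list alone. Both iron uptake genes were lower, 2 of 2, among them the siderophore synthase SidC, BBA_05179, with 0 and 0 reads against 32 and 108. All 3 of 3 conidiation and spore genes were lower, and the sporulation associated genes BBA_02156 and BBA_03826 had no endophytic read. Of the oosporein cluster 1 of 7 members was tested, the laccase BBA_08183, with 0 and 0 reads against 29 and 74. The tested list members came from tables chosen on these samples and are not independent evidence. This holds for BBA_08183 too: its cluster was set by locus tags, but its product description comes from those tables. Genes without an endophytic read passed the filter only through their fermentation reads, so they could only come out lower. Counts of 0 reads in both endophytic libraries do not show absence at this depth.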
